A study of Mus musculus with 2 samples.

How the data were processed

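H3K36me3 ChIP-seq of mouse embryonic facial prominence at 14.5 days was analysed from 4 deposited peak lists. Per the labels, replicate 1 was a pool of 24 embryos with its 2 technical replicates combined, and replicate 2 a pool of 34 embryos with 1. Per the text notes deposited with the lists, all are narrowPeak files on mm10: a list per replicate, a list called on both replicates pooled, and a list of replicated peaks derived from the other 3. The aligner, the peak caller with its version and threshold, and the rule for keeping a replicated peak are not given in the sources used here. Per the same notes, replicate 1's list was derived from its alignment and 1 other file, and replicate 2's from its alignment and 2 other files; whether the lists were made in different ways is not given in the sources used here.

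The authors' deposited lists give each peak's start and end, a signal value, and a −log10 p and −log10 q. The authors' signal value was read here as a fold enrichment over control (a ratio) from the usual narrowPeak layout and its range, since its definition is not given in the sources used here. The lowest −log10 p was 2.00 in replicate 1's list and 2.03 in replicate 2's, and the lowest −log10 q was 0.683 and 0.623. Fold and −log10 values are the authors' own and were used to describe, rank or filter peaks within a list. In the closing section, fold was also compared between X-linked and autosomal peaks within each replicate's list. There a gene's mean fold over both replicates' lists also served to match random genes to zinc finger genes. The lists hold no read counts, so depth per sample is unknown and no counting interval is given. Printed errors are the SD of the replicates' own lists (n = 2), except for intervals over genes (95%, 10000 bootstrap resamples) given for zinc finger genes. Part of the spread between replicates is a general difference in covered bases (115 Mb in replicate 1 and 103 Mb in replicate 2). Of replicated peaks, 71.2% were covered over at least 50% of their length in both replicates' lists.

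Genes came from GENCODE M21 on GRCm38, the assembly of mm10; chromosome lengths were taken from the RefSeq FASTA, and 0 peaks ran past a chromosome end. Chromosomes 1 to 19, X and Y were used. The 13, 34, 12 and 5 peaks on other scaffolds in the lists of replicate 1, of replicate 2, pooled and replicated were left out of the comparisons. Coordinates are printed 1-based. Within a list, 0 peaks overlapped.

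For every gene the percent of bases between its annotated start and end that lay in peaks was computed, without regard to strand. Signal of overlapping genes cannot be told apart in such lists, so another protein-coding gene that overlaps a named gene with replicated peaks is given beside it. A gene was called marked at 10% or more covered by replicated peaks. Marked genes were counted among 21221 protein-coding genes of at least 1 kb. A peak was called shared when at least 50% of its length was covered by the other replicate's list. The expected overlap came from 100 seeded circular shifts of the peaks along each chromosome. Position along the gene used marked genes of at least 5 kb that overlap no other protein-coding gene, in 10 equal parts. Exons were the union over transcripts. Coverage beyond gene ends used genes of that kind with no annotated gene within 10 kb on that side.

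Before the data were examined, 29 gene lists were fixed: 21 of named symbols and 8 defined by symbol patterns; 0 listed symbols lacked a match. They cover ubiquitously transcribed, ribosomal, mitochondrial ribosomal, cell cycle, signalling, H3K36, loose matrix, collagen, solute carrier, zinc finger, imprinted, long non-coding, palate, osteoblast, cartilage and craniofacial regulator genes, marker lists of muscle, epithelium, neuron, Schwann cell, endothelium, blood, liver and germ cells, and the Hox, histone, olfactory receptor, vomeronasal receptor and keratin-associated families. Lists share members: 17 of the collagen genes, 10 of the loose matrix genes, 9 of the osteoblast genes, 8 of the cartilage genes and 8 of the palate genes are also in another list. A list's median percent covered was placed among 10000 random lists of protein-coding genes, each member replaced by a gene drawn from the 200 nearest in length. These percentiles describe these libraries and are not p-values. For 27 of the 29 lists, a median of 0 would itself have stood above 2.5%, so the lower side says nothing there. Named genes followed a fixed rule: per list the 3 highest and 2 lowest by percent covered (longer genes first among ties); where a list had 6 or fewer marked or unmarked members, those; the 10 genes of at least 5 kb with the most covered bases; the 5 widest and 5 highest-fold replicated peaks; and the 5 genes of at least 5 kb, covered over at least 10% in either replicate, with the largest replicate difference in each direction. With 1 group and 2 replicates, no test between groups was possible.

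Alternatives were a −log10 q of at least 2, each replicate's own list, the pooled list, peaks closer than 1 kb merged, marking thresholds of 5% and 20%, other overlap rules, introns near exons only, random lists matched also on the number of protein-coding genes within 500 kb, and X-linked ratios by share of marked genes and without gene families. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1. The code was tested on simulated data: a 3' to 5' ratio of 3 was recovered as 2.992 and an exon to intron ratio of 2 as 1.998, over 1000 simulated genes each. Of 200 random lists of 30 genes, 4% lay in the top 2.5% and 0% in the bottom 2.5%; with 15 of 30 members drawn from marked genes, 86.5% lay in the top 2.5%.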

Results

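Trimethylation of histone H3 at lysine 36 (H3K36me3) is laid down over the bodies of transcribed genes, chiefly by the methyltransferase Setd2. Its distribution was measured by ChIP-seq in the embryonic facial prominence, the tissue that builds the jaws, palate and midface, taken from mouse embryos at 14.5 days. There was 1 group with 2 biological replicates, a pool of 24 embryos (replicate 1) and a pool of 34 embryos (replicate 2), both of mixed sex. No other tissue, age or treatment was part of the series, so no group was compared with another and no p-value was computed. The data were 4 peak lists on mm10. Replicate 1's own list held 195092 peaks covering 115 Mb, with a median width of 375 bases, and replicate 2's own list held 224783 peaks covering 103 Mb, with a median width of 311 bases. The pooled list held 186401 peaks covering 135 Mb, and the replicated list, which the authors derived from the other 3, held 124775 peaks covering 118 Mb with a median width of 601 bases. The lists give no read counts, so the depth behind each value is unknown. The spread between the 2 replicates is the only error given, apart from intervals over zinc finger genes in the closing section. Values below are percent of a gene body covered by replicated peaks where a single percent is given, and the mean of the replicates' own lists where an SD with n = 2 is given.

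The question of the first comparison was how far the 2 embryo pools gave the same genes and peaks. At a threshold of 10% of the gene body, 7905 protein-coding genes were marked in both replicates' own lists, 541 in replicate 1 alone and 235 in replicate 2 alone. Among named genes, Gpi1, a glycolytic enzyme, was covered over 77.5% of its length in replicate 1 and 76.8% in replicate 2, and Col1a1, the main collagen of bone and dermis, over 79.5% and 79.3%. Among genes of at least 5 kb, the widest gaps towards replicate 1 were at Tmem265 (74.1% against 33.9%), which overlaps Gm42715, Pdrg1 (68.8% against 30.3%), Erg28 (63.5% against 25.5%), Angptl7 (71.7% against 34.0%), a gene that overlaps Mtor, and Coq4 (47.2% against 9.92%), which overlaps Trub2. Towards replicate 2 they were at Bcam, a laminin-binding adhesion protein (35.4% against 7.03% in replicate 1), Asmt (36.5% against 8.28%), Zfp273 (33.9% against 10.2%), AU041133 (50.5% against 27.3%) and Zfp599 (75.3% against 53.0%). Of 7811 genes of at least 5 kb marked in either replicate, 6291 were covered more in replicate 1 and 1518 more in replicate 2, with a median difference of 5.01 percentage points. Peak by peak, 57.0% of replicate 1's peaks and 64.0% of replicate 2's had at least 50% of their length covered by the other list. After 100 random shifts of the other list along each chromosome these values reached at most 5.11% and 5.77%. Among the 10% of peaks with the highest fold enrichment, as the authors' own signal value was read, 93.1% of replicate 1's and 94.7% of replicate 2's were shared, and among the 10% with the lowest 37.8% and 43.6%. Across 21221 protein-coding genes of at least 1 kb, percent covered in the 2 replicates had a Pearson r of 0.975 and a Spearman rho of 0.964. Of these genes, 9859 had no covered base in replicate 1 and 9615 in replicate 2. Among the 8235 genes marked by replicated peaks, the Pearson r was 0.925. These are correlations across genes, which are not independent replicates.

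The second comparison asked where in the genome the mark lay. Protein-coding gene bodies, which make up 38.2% of the 21 chromosomes analysed, held 95.2% of the bases of the replicated peaks. The replicates' own lists gave 94.9% ± 0.483 (SD, n = 2). After 100 shifts of the replicated peaks the share lay between 38.4% and 44.2%. Exons of protein-coding genes held 23.3% ± 0.277 (SD, n = 2) of the bases against 3.52% of the genome. The 1 kb on either side of a protein-coding start held 0.374% ± 0.0117 (SD, n = 2) against 1.52% of the genome, below the lowest shifted value in both replicates (1.47% in replicate 1 and 1.48% in replicate 2). The 5 widest replicated peaks lay over Dnmt1, the maintenance DNA methyltransferase (chromosome 9, 20905257 to 20930341, 25085 bases), Kmt2d, a histone H3 lysine 4 methyltransferase (chromosome 15, 98832673 to 98856645, 23973 bases), the chromatin remodeller gene Smarca4 (chromosome 9, 21658312 to 21681512, 23201 bases), Prrc2b (chromosome 2, 32205692 to 32228469, 22778 bases) and the calcium pump gene Atp2a2 (chromosome 5, 122452051 to 122474726, 22676 bases). Their exonic share ranged from 8.82% in Smarca4 to 58.0% in Kmt2d. The rest was intron, except for 7.78% of the Dnmt1 peak and 6.45% of the Atp2a2 peak, which ran past the annotated 3' ends. The 5 replicated peaks with the highest fold enrichment stood at 17.3 to 19.3 fold. They lay over Zfp865, Ccdc106 and the overlapping models Gm44973 and 4632433K11Rik on chromosome 7 (5027411 to 5034223), over Zfp68 on chromosome 5 (138604636 to 138608835, and an intronic peak at 138609009 to 138610155), over Zfp146 on chromosome 7 (30160608 to 30164437) and over 2610008E11Rik on chromosome 10 (79062745 to 79068830). Zfp865, Zfp68 and Zfp146 encode zinc finger proteins. The exonic share of the strongest peak at Zfp68 was 75.9%, with 37.6% of its bases in coding sequence and 38.2% in untranslated sequence.

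The third comparison counted marked genes. Of 21221 protein-coding genes of at least 1 kb, 8235 (38.8%) had at least 10% of the gene body covered by replicated peaks, while 10625 had no covered base. The median coverage of the marked genes was 43.1%, with quartiles of 25.5% and 61.5%, and 413 were covered over at least 80% of their length. Of the 8235 marked genes, 7832 (95.1%) also passed the threshold in both replicates' own lists, which gave 8446 marked genes for replicate 1 and 8140 for replicate 2. The genes with the most covered bases included Fbn2, encoding the microfibril protein fibrillin 2 (138 kb of 202 kb; 58.8% ± 2.88, SD, n = 2), Wdfy3 (132 kb; 49.3% ± 1.50), the translation factor gene Eif4g3 (119 kb; 49.8% ± 7.82), the ubiquitin ligase gene Ubr4, which overlaps Emc1 (118 kb; 78.3% ± 7.21), and the cytoskeletal linker gene Macf1 (114 kb; 30.7% ± 3.93). Vps13d (113 kb), Dock1 (107 kb), which overlaps Fam196a, and Trio (107 kb) followed, the last pair being guanine nucleotide exchange factors. The highest totals, 517 kb in Gm20388 and 261 kb in Fgfr2, came from annotated models of 4435 kb and 2961 kb that span many other protein-coding genes, so their covered bases cannot be assigned to a single gene. On autosomes the marked share ran from 32.0% of genes on chromosome 14 to 49.7% on chromosome 8, while chromosome Y had 0 marked genes of 163.

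The fourth comparison set 29 gene lists, fixed before the data were examined, against random lists of the same gene lengths. Genes of growth and division were marked almost throughout: 34 of 35 cell cycle genes (median coverage in the replicates 56.2% ± 5.61, SD, n = 2), 28 of 30 ribosomal protein genes (61.1% ± 7.86), 65 of 78 mitochondrial ribosomal protein genes (38.2% ± 4.96) and 28 of 30 ubiquitously transcribed genes (48.8% ± 7.09). Cdk1, the kinase that drives entry into mitosis, was covered over 76.5% ± 5.22 of its length, and the replication helicase genes Mcm3 and Mcm2 over 75.8% ± 2.27 and 71.7% ± 4.88. Cdk6 was the 1 unmarked cell cycle gene, at 2.30% ± 0.786. Rps3, Rps5 and Rpsa led the ribosomal protein genes at 79.7% ± 2.36, 74.8% ± 1.51 and 73.8% ± 10.7. Their unmarked members were Rps14 (7.23% ± 1.30), whose 31.4 kb model overlaps Ndst1, and Rps23 (3.31% ± 3.83, but 9.98% by replicated peaks, just under the threshold). Mrpl37, Mrpl22 and Mrpl19 headed the mitochondrial ribosomal proteins at 69.1% ± 6.50, 67.7% ± 7.46 and 63.5% ± 3.51 (Mrpl19 overlaps Gcfc2), while Mrpl36 and Mrpl41 had no covered base. Gpi1, Eef2, the translation elongation factor, and the chaperone gene Hsp90ab1 led the ubiquitously transcribed list at 77.2% ± 0.519, 78.2% ± 5.76 and 73.5% ± 16.5, and Gusb (4.85% by replicated peaks) and Hprt (9.69%) fell short of the threshold there. Both passed it in replicate 1's own list, and Hprt also in replicate 2's. The median of each of these 4 lists by replicated peaks, the measure used for all percentiles of lists, lay above that of all 10000 random lists.

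The matrix of loose mesenchyme, the signalling pathways of facial growth and the H3K36 machinery itself were also marked above random lists. Of 30 matrix genes, 28 were marked (42.7% ± 0.152, SD, n = 2), with fibronectin, Fn1 (chromosome 1, 71585520 to 71653200), at 84.7% ± 4.42, Col6a1 at 75.0% ± 2.69 and thrombospondin 1, Thbs1, at 68.3% ± 6.48. The unmarked members were Loxl2 (1.43% ± 0.245) and Col14a1 (2.92% ± 0.460). Of 43 signalling genes, 34 were marked (24.0% ± 2.96), led by the hedgehog receptor gene Ptch1 (51.7% ± 1.46), the Wnt target Axin2 (50.8% ± 2.73) and the Notch ligand gene Jag1 (43.2% ± 0.243). Hhip (0.410% ± 0.580) and Fzd1 (15.4% in replicate 1 and 0% in replicate 2) were at the bottom. Of 26 genes for H3K36 methyltransferases, demethylases and readers, 23 were marked (50.4% ± 6.14). Kdm4a, an H3K36 demethylase, was covered over 86.7% ± 3.43, Brpf1 over 71.9% ± 8.77 and the elongation factor gene Supt6, which overlaps Sdf2, over 72.9% ± 0.823. Dnmt3b (6.48% ± 0.639), Phf19 (8.69% ± 3.51) and Kdm2b (9.79% ± 2.02), which overlaps Rnf34, were unmarked in the replicated list, although Phf19 and Kdm2b passed 10% in replicate 1's own list. Of 424 zinc finger genes of the Zfp, Zkscan and Zscan families, 288 were marked (27.4% ± 1.70), up to Zfp869 at 94.6% ± 7.61, Zfp110 at 87.7% ± 2.70 and Zfp335, which overlaps Pcif1, at 83.8% ± 0.299, while Zfp804b and Zfp385b had no replicated peak. The medians of the signalling list (percentile 99.96), the matrix, H3K36 and zinc finger lists (each at percentile 100) were the other 4 of 8 lists in the top 2.5% of random lists.

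Lists of the skeletal and facial programmes were mixed. Of 40 transcriptional regulators of craniofacial mesenchyme and neural crest, 9 were marked, and the list's median in the replicates was 2.41% ± 0.913 (SD, n = 2). Six4 reached 41.3% ± 2.51, Snai2 31.6% in replicate 1 and 29.7% in replicate 2, and Prrx1, a homeobox gene of facial mesenchyme (chromosome 1, 163245119 to 163313710), 30.0% ± 4.71, while Pax7 and Tfap2b had no covered base. Of 29 palate and cleft genes, 13 were marked (7.51% ± 2.15), led by Pdgfra (68.5% ± 3.67) and Ptch1 (51.7% ± 1.46), with Tgfb3, which overlaps Ttll5, at 47.4% ± 9.17. Gabrb3 had no covered base, and Fgf10 had none in replicate 1 and 0.779% in replicate 2. Of 25 osteoblast and bone matrix genes, 11 were marked (4.04% ± 0.305): Col1a1 (chromosome 11, 94936224 to 94953042) stood at 79.4% ± 0.143, Col1a2 at 77.6% ± 2.98 and Ifitm5, which overlaps Gm45717, at 60.5% ± 19.2, whereas Phex had no covered base and Tnfrsf11b stood at 0.400% ± 0.566. Of 25 cartilage genes, 7 were marked (0.873% ± 0.150), with Fgfr3 at 33.2% ± 12.6, Col2a1, the main collagen of cartilage, at 33.4% ± 16.6 and Pth1r, which overlaps Myl3, at 26.2% ± 4.29, and with Hapln1 (0%) and Epyc (0.229% ± 0.324) lowest. Of 44 collagen genes, 17 were marked (3.35% ± 0.261), and Col19a1 and Col4a6 had no replicated peak. Of 30 imprinted genes, 16 were marked (12.4% ± 0.258): Igf2r stood at 58.1% ± 5.32, Nnat, which overlaps Blcap, at 71.2% ± 29.5 and Meg3 at 45.6% ± 22.2, whereas Usp29 and Snrpn, which overlaps Snurf and Gm38393, stood under 1%. Of 22 long non-coding RNA genes, 9 were marked (7.62% ± 1.64), led by Snhg1 (71.2% ± 0.429) and Malat1 (62.4% ± 14.9), with no replicated peak in Sox2ot or Rmst. By replicated peaks, the medians of 6 of these lists stood at percentiles from 40.9 for the cartilage genes to 92.6 for the imprinted genes, none in the top 2.5%. The regulators' median by replicated peaks was 0, as was that of most of their random lists, so it could not be placed there; by the replicates' own lists it stood at percentile 69.9 in replicate 1 and 78.5 in replicate 2. Of 371 solute carrier genes, 134 (36.1%) were marked (0.562% ± 0.0630), against 38.8% of all protein-coding genes of at least 1 kb. That share is not matched on length, and random lists of like gene lengths had 162 of 371 marked at the median. By replicated peaks the median of the solute carrier genes was 0, at percentile 0.325, and this was the 1 list under 2.5%. Slc38a2, an amino acid transporter, was still covered over 87.6% ± 0.476 and Slc39a6, which overlaps Elp2, over 72.4% ± 4.29, with Slc20a1 at 65.2% ± 12.5, while Slc9a9 and Slc7a11 had no replicated peak.

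**Figure D1:**
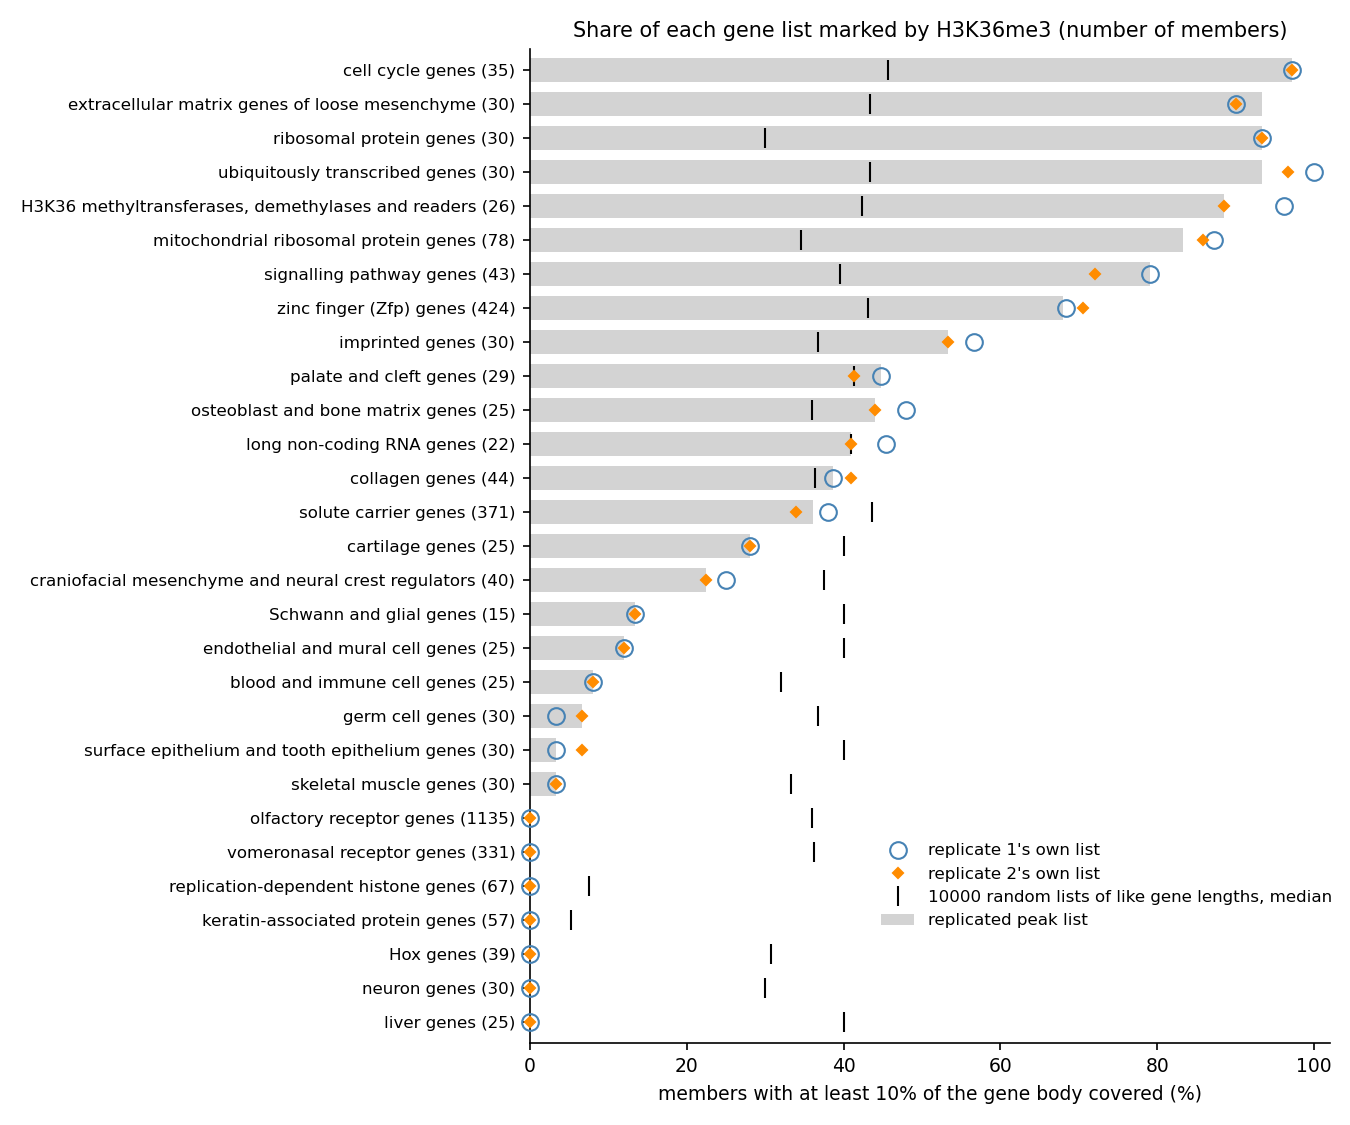
Percent of the members of each fixed gene list with at least 10% of the gene body covered (horizontal axis); grey bars are the replicated peak list, circles and diamonds the own lists of replicate 1 and replicate 2, and black ticks the median of 10000 random lists of like gene lengths. The 34 of 35 marked cell cycle genes stand at the top, and 7 lists, from olfactory receptor to liver genes, have 0 marked members.

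Markers of other cell types, those that a facial prominence can hold and those of liver and germ cells, were rarely marked. Several gene families that are not cell type markers had no marked member. In skeletal muscle 1 of 30 genes was marked, Tpm2, a tropomyosin (24.1% ± 5.60, SD, n = 2), and Mef2c (5.33% ± 2.27) and the titin gene Ttn (2.37% ± 1.81) came next, with no replicated peak in Dmd or Myom1. In surface and tooth epithelium 1 of 30 was marked, Esrp2 (33.3% ± 5.25), which overlaps Nfatc3, followed by Dsp (7.02% ± 5.78) and Lama5 (6.92% ± 0.637), while Edar had no covered base and Grhl2 stood at 0.717% ± 0.797. In the list of endothelial and mural cell genes 3 of 25 were marked: Notch3 (52.0% ± 1.37), Pdgfrb (50.3% ± 1.33) and Eng (15.1% ± 2.33), which overlaps Fpgs. The endothelial receptor genes Flt1 and Tek had no covered base. Which cells the coverage of Notch3 and Pdgfrb came from was not tested. In Schwann cells and glia 2 of 15 were marked, Pmp22 (46.1% ± 4.45) and S100b (13.8% ± 8.96), which overlaps Dip2a. S100b stood at 20.1% in replicate 1 but 7.43% in replicate 2. Erbb3 stood at 9.79% ± 2.36, with 8.12% in replicate 1 and 11.5% in replicate 2, and Mbp and Cdh19 had no covered base. In blood and immune cells 2 of 25 were marked, Fcer1g (17.8% ± 1.86) and Cx3cr1 (15.8% ± 2.79), whose 168 kb model overlaps Wdr48 and at least 4 other genes, with Csf1r, which overlaps Hmgxb3, at 5.03% ± 1.86 and no covered base in Ptprc or Adgre1. Among germ cell genes 2 of 30 were marked, Rec8 (18.0% ± 9.60) and Brdt (10.3% ± 2.70, but 8.35% in replicate 1's own list). Tex15 stood at 0.819% ± 0.0544, and Spata16 and Tex11 had no covered base. None of 30 neuron genes was marked, the highest being Map2 (0.604% ± 0.202) and Ntrk2 (0.521% ± 0.0533), and Nrxn1 and Ntrk3 had no covered base. None of 25 liver genes was marked, where Hnf1a, which overlaps 2210016L21Rik, stood at 4.25% ± 0.694 and Cps1 and Serpina1b at 0%. None of 39 Hox genes, the 3 longest being Hoxc5, Hoxa3 and Hoxd3, had a replicated peak. The same held for 67 replication-dependent histone genes (among them Hist1h2be, Hist1h2bc and Hist1h1d), 1135 olfactory receptor genes (Olfr56, Olfr643 and Olfr164), 331 vomeronasal receptor genes (Vmn2r7, Vmn2r60 and Vmn2r71) and 57 keratin-associated protein genes (Krtap15, Krtap14 and Krtap16-1). The histone genes had a median length of 0.539 kb, and their random lists had 5 of 67 members marked at the median. Random lists often had a median of 0 too, so 27 of the 29 lists could not have come under 2.5% by their median, these 13 included, and only the solute carrier and collagen lists could. By number of marked members, a measure added after seeing the data, 15 lists lay under 2.5%, these 13 with the solute carriers and the craniofacial regulators (percentile 2.25). The low place of the regulators depends on that measure, since their medians in the replicates' own lists stood at percentiles 69.9 and 78.5.

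**Figure D2:**
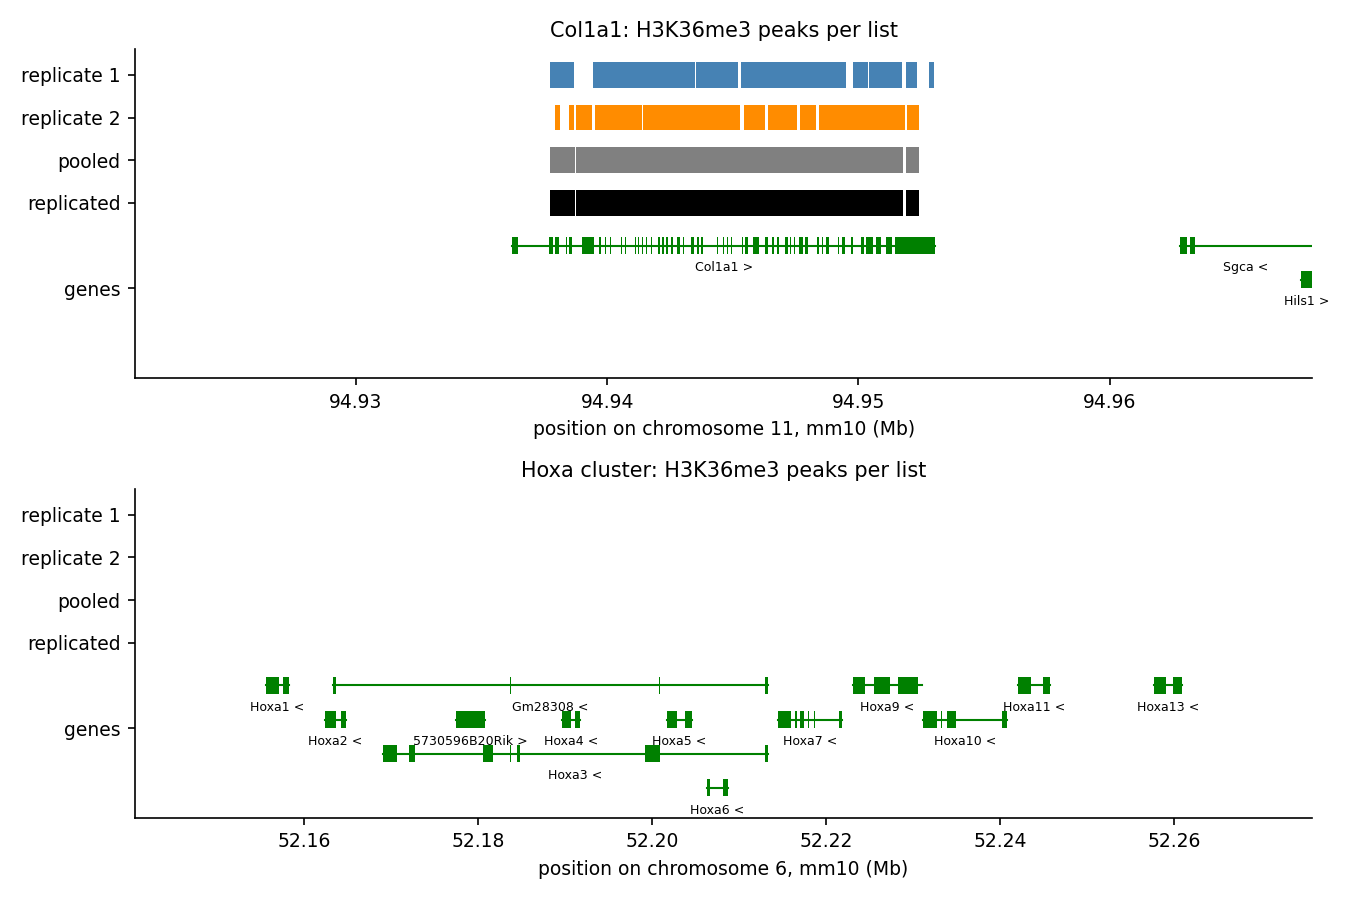
H3K36me3 peaks in the 4 lists (coloured blocks, rows) over Col1a1 on chromosome 11 and the Hoxa cluster on chromosome 6, with position in Mb on mm10; green lines are annotated protein-coding genes, green blocks their exons, and > or < the strand. Replicated peaks cover 86.1% of Col1a1, and 0 replicated peaks lie on any Hox gene.

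The fifth comparison followed the mark along the gene. In 5262 marked genes of at least 5 kb that overlapped no other protein-coding gene, coverage rose from 5.17% ± 0.490 (SD, n = 2) in the first of 10 equal parts of the gene body to 56.8% ± 5.05 in part 9, and was 53.3% ± 5.09 in the last. The last 3 parts were covered 3.05 ± 0.0367 (SD, n = 2) times as much as the first 3, and in 4845 of the genes (92.1%) the 3' side was covered more. Genes of 5 to 10 kb had 0.619% ± 0.150 of the first part covered and a ratio of 6.67 ± 0.715, whereas genes of 20 to 50 kb had 6.64% ± 0.715 and a ratio of 2.47 ± 0.0142. For genes over 100 kb the ratio was 3.60 ± 0.224. In 8619 unmarked genes of the same kind, coverage went from 0.401% ± 0.00752 in the first part to 2.79% ± 0.243 in the last.

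**Figure D3:**
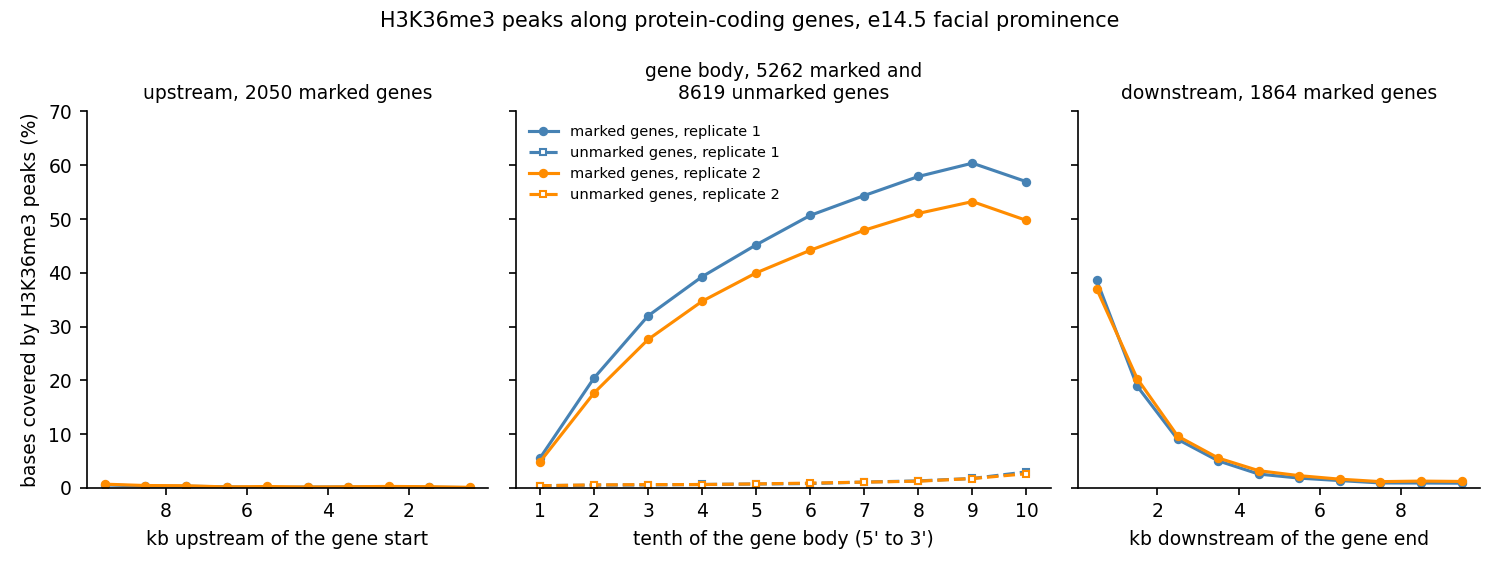
Percent of bases covered by H3K36me3 peaks (vertical axis) in each replicate's own list, in 1 kb steps upstream of the gene start, in 10 equal parts of the gene body, and in 1 kb steps downstream of the gene end; filled circles are marked and open squares unmarked genes. Coverage of the 5262 marked genes rises to 60.4% in replicate 1 and 53.2% in replicate 2 in part 9. Downstream values are over the 1864 of these genes with no annotated gene within 10 kb there, and are 38.7% and 37.0% in the first kb.

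The sixth comparison set exons against introns in the same marked genes, leaving out first and last exons. All introns were kept, those beside the first and last exons included, so position along the gene was not fully matched. Percents are of bases summed over genes, so genes with long introns weighed more in the intron percent than in the exon percent. The ratio is thus not a contrast within each gene, and how far this weighting moved it was not tested. In 5172 genes with 62442 internal exons, 59.8% ± 5.03 (SD, n = 2) of exon bases and 30.1% ± 2.65 of intron bases were covered, a ratio of 1.99 ± 0.00819. Within 500 bases of an exon, introns were covered over 49.9% ± 5.02, which brought the ratio to 1.20 ± 0.0200. Each ratio differed from 1 by more than the SD of the replicates.

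The seventh comparison set the X chromosome against the autosomes. Each pool mixed the sexes, so X was present in fewer copies than an autosome, and no correction was made for this here. X-linked protein-coding genes were covered over 4.63% ± 0.0852 (SD, n = 2) of their length on average, against 16.5% ± 1.63 for autosomal genes, a ratio of 0.282 ± 0.0227. Of 877 X-linked genes, 114 (13.0%) were marked, against 8121 of 20181 autosomal genes (40.2%). The 5 X-linked genes most covered by replicated peaks, chosen after their values were seen, were Maged1 (66.5% ± 3.03), the filamin gene Flna (61.5% ± 5.38), Kdm5c, a histone H3 lysine 4 demethylase (59.9% ± 1.71), Hcfc1 (57.2% ± 2.39) and Rbmx (54.1% ± 1.12). By the mean of the replicates, Eif2s3x (55.7% ± 0.222) and Rbm3 (54.5% ± 8.20) also stood above Rbmx. Phex, Dmd, Tex11 and Col4a6 on X had no replicated peak. In the replicates' own lists, 15.5% ± 0.161 (SD, n = 2) of X-linked and 40.4% ± 1.08 of autosomal genes passed the marking threshold. The ratio of these shares, averaged over the replicates and used in place of mean coverage, was 0.384.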

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

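Replicated peaks also lay on scaffolds that are assigned to a chromosome but are not part of its assembled sequence, and these entered no comparison. There were 5 such peaks, for which these lists give no expected number to compare with: 2 on scaffolds of chromosome 4, over the gene models CAAA01118383.1 and CAAA01147332.1 at 11.7 and 11.3 fold enrichment, and 3 on a scaffold of chromosome X, over Vamp7 (2 peaks, 2.66 and 3.49 fold) and Tmlhe (2.99 fold).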

How the results depend on the processing

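The 8 lists in the top 2.5% of random lists and the 1 in the bottom 2.5% stayed the same lists under the stricter peak threshold, either replicate alone, the pooled list, merged peaks and matching on gene density. Number of marked members, chosen after seeing the data, gave 15 lists below 2.5%, since a count can fall below random lists where a median of 0 cannot; by the median only 2 of 29 lists could. Marked genes ranged from 6862 (20% threshold) to 9115 (5% threshold). Without replicate 1 and without replicate 2 the counts were 8140 and 8446, and 96.2% and 98.4% of the main genes stayed marked. Of the main marked genes, 5734 overlap no other protein-coding gene, a count over fewer genes that was added after seeing the data. Shared peaks (mean of both directions 60.5%) went to 72.9% at 1 base of overlap, 33.6% at a reciprocal 50% and 50.8% with peaks closer than 1 kb merged; leaving out a replicate leaves no pair to compare. The share of bases in genes ranged from 94.6% to 95.3% with either replicate left out. The 3' to 5' ratio was 3.17 at a −log10 q of at least 2, 2.94 for the pooled list, 2.94 for merged peaks, 2.95 for genes marked at 20% and 3.18 for the replicated list. Those at that q, for the pooled list and for merged peaks used the genes marked under each setting; over the main genes, added after seeing the data, they were 3.17, 2.92 and 2.93. The exon to intron ratio was 2.05 at that q, 2.01 for the pooled list and 1.79 for merged peaks, each over the genes marked there, but 2.05, 1.88 and 1.70 over the main genes, so the pooled list moved to opposite sides of the main 1.99 with the choice of genes. It was 2.00 for the replicated list and 1.20 for introns near exons, which include those beside the first and last exons. The X to autosome ratio was 0.258 at that q, 0.325 for merged peaks and 0.239 for the replicated list. By share of genes that passed the marking threshold in the replicates' own lists, it was 0.384. Each of these ratios kept its side of 1, and the cause of these shifts was not tested beyond the alternatives' own construction. Of 148 named genes, 6 changed their marked call without replicate 1 (Coq4, Dsp, Erbb3, Gm20388, Hprt and S100b), 8 without replicate 2 (Asmt, Bcam, Brdt, Fzd1, Gusb, Hprt, Kdm2b and Phf19), 8 with the pooled list, 2 with merged peaks and 0 at the stricter q. No paired analysis was possible because there was 1 group. Read depth is unknown, so a gene without a peak may hold the mark below what these lists can show.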

Other observations

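Every test of an explanation below was chosen after its pattern was seen, and the tests of gene length and of the direction in isolated zinc finger genes after their results were seen as well. The mark ran past the annotated ends of genes but hardly before their starts. In 1864 marked genes with no annotated gene within 10 kb downstream, the first kb beyond the gene end was covered over 37.9% ± 1.14 (SD, n = 2), the next over 19.6% ± 1.00, the fifth over 2.87% ± 0.443 and the tenth over 1.03% ± 0.226. In 2050 genes with none upstream, the first kb before the start was covered over 0.0678% ± 0.0359. Annotated genes of any kind held 96.0% of replicated bases. Most of the rest lay in domains (peaks within 5 kb joined) that touch a gene, and the 192 domains that touch none held 0.114% of replicated bases. The largest was on chromosome Y (90735553 to 90745838, 5.38 kb covered), 7218 bases from the pseudogene Mid1-ps1, and the next were near Pisd-ps2 on chromosome 17 (3069909 to 3076285) and near Rbm12b2 on chromosome 4 (12102090 to 12107596).

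Zinc finger genes stood out by peak strength. They hold 2.08% of replicated peaks and 0.480% of the genome, yet 49 of the 100 replicated peaks with the highest fold enrichment, 27 of the top 100 in replicate 1's own list and 52 in replicate 2's.

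X-linked genes were less covered than autosomal genes, at a ratio of 0.282. As the whole cause, a poorer content of widely transcribed genes on X would bring pairs of such genes near parity. Its share as a partial cause was not tested. The 39 fixed pairs each held an X-linked and an autosomal gene that most cells transcribe, not matched on length or transcription level. Over them the ratio of medians was 0.412 (0.406 in replicate 1 and 0.418 in replicate 2), short of parity. The 0.282 is instead a ratio of means over all genes. The X-linked gene was lower in 33 pairs. Among these were Atrx and Chd4 (16.4% ± 0.0413 against 80.8% ± 2.96) and Huwe1 and Ubr4 (32.3% ± 3.19 against 78.3% ± 7.21), while in the other 6 pairs Kdm5c, Usp9x, Stag2, Cdk16, Bcap31 and Dkc1 (which overlaps Mpp1) stood above their partners. Pools of mixed sex hold fewer copies of X than of an autosome, so fewer reads from X are built into the design. What part lower read depth on X has in the lower coverage cannot be told apart. At a −log10 p of 6 to 8 the median fold of X-linked peaks was 1.02 times that of autosomal ones. This was above 1.00, which would have spoken against lower depth, and short of the 5% excess that lower depth required. No explanation by sex or by X inactivation was tested, since each pool mixed the sexes.

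Craniofacial regulators were marked in 9 of 40 cases and loose matrix genes in 28 of 30. This is a difference of 70.8 percentage points, and short gene bodies or high GC content as its main cause would give random genes of the same lengths or GC contents much of it. Random lists matched on length to the matrix genes and to the regulators differed by 5.83 points at the median, and lists matched on GC content by -4.17 points; the observed difference exceeded that of all 10000 random pairs in both cases. Earlier tests, the share marked among 20 long regulators (5) and among 25 GC-rich members of well marked lists (25), decided nothing, since the lists' totals fixed their outcome. No biological explanation was tested, and the share of cells that transcribe each gene stays open.

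Zinc finger genes did not follow the general trend of higher coverage in replicate 1: of 290 with a mean coverage of at least 10%, 162 were higher in replicate 2, and the median difference (replicate 1 minus replicate 2) was -1.30 percentage points against 5.29 over 7933 other genes, at percentile 0 of random lists matched on mean coverage. GC content of the gene body, peak strength (stronger peaks losing less length in the list with narrower peaks) and reads shared between neighbouring paralogs each predicted a percentile outside the lowest and highest 2.5% once matched; it stayed at 0 with GC content matched, at 0 with the authors' fold matched and at 0 for the 91 genes with no other list member within 500 kb, whose median difference was 1.06 against 5.53. That 1.06 lay on the side of replicate 1 (95% bootstrap interval over genes, -0.858 to 2.92). Since this interval includes 0, shared reads cannot be told apart for the direction alone. The 199 genes with a list neighbour stood at -2.26 (-3.27 to -1.21). Genes of that group lie near each other but were resampled as independent, so their interval may be too narrow. Only list members counted as neighbours, so the 91 genes may still lie near other paralogs. A part played by reads shared between paralogs stays open. The unequal number of files from which the authors derived the replicates' lists, and a difference between the embryo pools, stay open too. No biological explanation was tested.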
